A study of Homo sapiens with 14 samples.

How the data were processed

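HuR iCLIP and control IgG libraries from MCF-7 cells were compared from their processed peak files. Per the labels, cells received water or 3.5 µM doxorubicin for 6 h and were taken whole or separated by detergent lysis into nuclei and cytosol. Each of the 6 HuR groups has 2 libraries, and 2 IgG libraries come from untreated whole cells. File names number replicate 1 of the nuclear and cytosolic libraries differently from the labels, and the labels were followed. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

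Reads were aligned to hg19, and Bowtie2 2.2.5, SAMtools 1.1 and Picard were used, per the submitters' processing notes. Piranha is named, per the file headers, in 4 files, those of replicate 1 of the nuclear and cytosolic groups, with a value of 0.95. The peak caller of the other files is not given in the sources used here. Each deposited file holds peaks called in 1 library, made of 50-nt bins, with the strand, a RefSeq gene and a whole count of reads per peak, per the file headers. Peaks lay on the strand of their gene and no more than 500 nt past its 3′ end, as tested on the files. No peak lay on the mitochondrial chromosome.

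Counts were summed per gene in each library. Of 14480 gene symbols 13087 are current in the reference table, 982 are synonyms and 411 have no match; the files' symbols were kept. The lists are censored, since the smallest listed peak held between 5 and 19 reads depending on the library. A gene without a peak is therefore described as having no listed peak and its libraries' levels are given. The report prints no fold change of a single gene against such a group. The closing section prints a few fitted values of that kind, named there as neither folds nor directions. Medians and means over lists, positions or all genes include such fitted values, unless given for members with peaks in both groups. Sums over peaks called separately also move with how much was called, so covered length and reads per covered nucleotide are given for nuclei and for the extremes.

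The 12 HuR libraries were fitted together with edgeR 4.0.16 (quasi-likelihood, 1 coefficient per group, TMM scaling, filterByExpr; 12539 genes kept) in R 4.3.3, and HuR was compared with IgG in a separate fit of 4 libraries (9360 genes). P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Comparisons were doxorubicin against untreated in whole cells, nuclei, cytosol and their mean, nucleus against cytosol in each treatment and their mean, and the difference between the doxorubicin effects in nucleus and cytosol. The fit with all 12 libraries assumes 1 spread for all groups.

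Gene lists were written before the data were examined, as were the comparisons, the named-gene rule and the alternatives, except those given in the closing section as chosen later. The 15 lists are p53 targets, DNA repair, immediate-early and AU-rich messages, known HuR targets, cell cycle and mitosis, ribosomal proteins, replication histones, RNA-binding and splicing factors, cleavage and polyadenylation machinery, estrogen response, nuclear-retained long non-coding RNAs, mitochondrial-encoded genes, abundant small non-coding RNAs, genes over 200 kb and markers of other cell types. They come from general knowledge, not from these samples, and some genes stand in more than 1. The mitochondrial-encoded list has no member in the files, leaving 14. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 112 tests. Alternatives were an estimated correlation, which called 0 lists, and fry, which called 12, against 23. All 12 fry calls were for nucleus against cytosol, so none of the list calls with doxorubicin held with fry.

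Genes were named by rule: those past the threshold without overlap between the groups' libraries and with a mean of at least 50 CPM in the higher group, the 10 largest in each direction; up to 4 members of each list past the threshold, or its 2 most abundant members; where fewer than 3 passed, the 5 smallest p-values; the 3 peaks with most reads per group; and 8 genes always given (ELAVL1, MALAT1, NEAT1, CDKN1A, MDM2, MYC, CCND1, ACTB). MRPS6 in nuclei, and SCD and MIR6087 in the IgG comparison, were added after their values were seen.

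The planned split into introns and untranslated regions could not be made, because the files give gene intervals without exons. In its place, peaks were divided by their midpoint into gene end (within 5 kb of the annotated 3′ end, or past it) and body. A search for HuR motifs was not run, since no genome sequence was at hand. Gene ends and bodies were compared within genes in edgeR (6256 genes), and shares of reads by exact two-sided permutation within preparation or treatment. Peak sharing was counted with bedtools 2.31.1 at an overlap of 1 nt.

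Alternatives were DESeq2 1.42.0, total-read and upper-quartile scaling, no filter, genes with a peak in all 12 HuR libraries, peaks of at least 10 reads, removal of peaks overlapping an IgG peak, only the libraries compared, a block for the replicate number, and leaving out each library. On simulated counts with 200 changed genes among 12539 at the fitted dispersion, the nuclear comparison recovered 0% of genes changed 2-fold and 0% changed 4-fold, and the mean over preparations 9% and 52%. At a much smaller dispersion, simulated for comparison, the nuclear comparison recovered 63% and 99%. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.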

Results

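HuR, encoded by ELAVL1, is an RNA-binding protein known to contact U-rich and AU-rich stretches of introns and 3′ untranslated regions. Its contacts were mapped by iCLIP, in which ultraviolet light links protein to RNA in intact cells and the RNA recovered with an antibody is sequenced. The cells were MCF-7, an estrogen receptor-positive human breast cancer line, given water or 3.5 µM doxorubicin, a DNA-intercalating topoisomerase II poison, for 6 h. HuR libraries came from whole cells, nuclei and cytosol, with 2 libraries in each of 6 groups. Another 2 libraries were made with control IgG from untreated whole cells, giving 14 libraries in 7 groups. Each library comes with its own list of peaks, and each peak carries a read count and 1 gene.

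Reads in listed peaks numbered 6000409 and 11374318 in untreated whole cells and 3900368 and 7375670 in doxorubicin-treated whole cells. In nuclei they numbered 25117463 and 11094184 without and 3431735 and 8675225 with doxorubicin. The cytosolic libraries held 5385488 and 17032452 reads without and 6064754 and 16610048 with doxorubicin, and the IgG libraries 2203059 and 352186. Among the HuR libraries, covered length ran from 29417.5 kb in untreated nuclear replicate 1 to 3385.6 kb in doxorubicin cytosolic replicate 1, at 0.854 and 1.79 reads per covered nucleotide. Untreated nuclear replicate 2 covered 20098 kb at 0.552 reads per nucleotide. The doxorubicin nuclear libraries covered less, 13042 and 18344 kb, at 0.263 and 0.473 reads per nucleotide. The smallest listed peak held between 5 and 15 reads in the HuR libraries and 5 or 19 in the IgG libraries, so a gene without a peak is described as having no listed peak, not as unbound. Replicates of 1 group shared 58.1% of their peaks on average over 12 directed pairs (range 28.2 to 88.4), against 51.0% for the same preparation under the other treatment.

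The peaks with the most reads lay in a few abundant transcripts (hg19 coordinates). In nuclei and whole cells the leading peak was in MALAT1, a nuclear long non-coding RNA, at chromosome 11, 65266501 to 65273550, with 3.65% of the reads of doxorubicin nuclear replicate 2. NEAT1, the scaffold RNA of paraspeckles, held the next peak in untreated nuclei, at 65190251 to 65208100 with 0.890% of the reads of replicate 1. A peak inside KCNQ1, a potassium channel gene, at chromosome 11, 2655601 to 2661400, took 1.13% of the reads of doxorubicin nuclear replicate 2. In cytosol the leading peaks were in SCD (stearoyl-CoA desaturase) at chromosome 10, 102120451 to 102124600, CANX (calnexin) at chromosome 5, 179155551 to 179158600, and ACTB (β-actin) at chromosome 7, 5566751 to 5567550. These 3 took 2.72%, 2.08% and 1.73% of the reads of untreated cytosolic replicate 2. SCD, ACTB and CANX also held the leading peaks of IgG replicate 1, with 3.23%, 2.46% and 1.84% of its reads.

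HuR against IgG in untreated whole cells asks which genes took a larger share of the reads with the HuR antibody than with IgG. Scaling to library size makes it a test of relative composition only. It does not measure how much more RNA the HuR antibody recovered in all. ACTB stood at 3368 and 4357 CPM (counts scaled to library size) in the HuR libraries and 25876 and 2334 in the IgG libraries. SCD stood at 2187 and 2182 against 32809 and 2595. IgG replicate 2 was led by MIR6087, a locus holding rRNA-like sequence, at 114658 CPM against 1200 in IgG replicate 1. Loci of that kind took 39.3% of the reads of IgG replicate 2, and the IgG libraries shared 19.4% of their peaks with each other. None of 9360 genes passed an adjusted p of 0.05 in edgeR, with 3408 below an unadjusted 0.05 (3345 higher with HuR) and 2995 past the threshold in DESeq2. The 5 genes with the smallest p, ABCD1, DNTTIP1, CHMP4C, ASB9 and CLEC4GP1, had no listed IgG peak and an adjusted p of 0.0531. They stood at 3.17 to 4.13 CPM in the HuR libraries. At such levels the IgG libraries, with 2203059 and 352186 reads and smallest listed peaks of 19 and 5 reads, would list no peak. The lack of an IgG peak is thus no sign of enrichment for them. How many of the 3345 share this limit was not counted. The count rose to 7318 without IgG replicate 2 and 1956 without IgG replicate 1, and was 4075 with peaks of at least 10 reads.

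Doxorubicin against untreated nuclei asks which RNAs gained or lost HuR-linked reads in the compartment where introns are removed. ACTB (chromosome 7, 5566779 to 5570232) rose from 996 ± 36.7 to 3574 ± 45.2 CPM (reads in a gene's listed peaks scaled to effective library size; mean ± SD, n = 2), a log2 fold change of 1.84 ± 0.22 (SE). MRPS6, a mitochondrial ribosomal protein gene (chromosome 21, 35445823 to 35515334), rose from 95.1 ± 12.1 to 2238 ± 197 CPM (log2 4.56 ± 0.48, adjusted p = 0.0174). PTPRG, a receptor tyrosine phosphatase gene of 733331 nt (chromosome 3, 61547243 to 62280573), rose from 955 ± 100.2 to 8785 ± 37.5 CPM. NUSAP1, a mitotic spindle protein, rose from 27.9 ± 0.842 to 421 ± 229 CPM, and PTMA, encoding prothymosin α, from 121 ± 20.4 to 832 ± 68.0 CPM. Among the genes that fell were the ubiquitin-conjugating enzyme UBE2E3 (338.8 ± 5.72 to 6.08 ± 3.67 CPM), the transcription elongation regulator TCERG1 (368 ± 66.1 to 13.8 ± 10.4 CPM) and filamin B, FLNB (312 ± 125 to 13.6 ± 6.62 CPM). In all, 369 of 12539 genes passed an adjusted p of 0.05, 271 higher and 98 lower, with adjusted p = 0.0174 for ACTB, PTPRG and NUSAP1, 0.0206 for PTMA, 0.0176 for UBE2E3, 0.0237 for TCERG1 and 0.0248 for FLNB.

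Of the genes that rose in nuclei, 55 had no listed peak in either untreated nuclear library. USP50, a ubiquitin-specific protease homologue (chromosome 15, 50792759 to 50838902), held 430.4 and 404.6 CPM after doxorubicin. MYRFL held 320 and 345 CPM, AMPD1 (muscle AMP deaminase) 297 and 172, TOMM20L 178.5 and 141.5, the GABA transporter gene SLC6A13 139 in both libraries, and the mannose receptor family gene MRC2 189.5 and 78.2. Conversely, 24 of the genes that fell had no listed peak after doxorubicin, among them SGCG at 314 and 147 CPM in untreated nuclei and the replication factor CDC45 at 52.8 and 75.9. Where both groups had peaks, the median log2 fold change was 3.01 over 216 genes that rose and −2.99 over 74 that fell. Other large falls with peaks on both sides were CRADD (−5.29 ± 0.72), HSD17B4 (−4.99 ± 0.73) and SIDT1 (−4.51 ± 0.66), each with adjusted p = 0.0174.

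**Figure D1:**
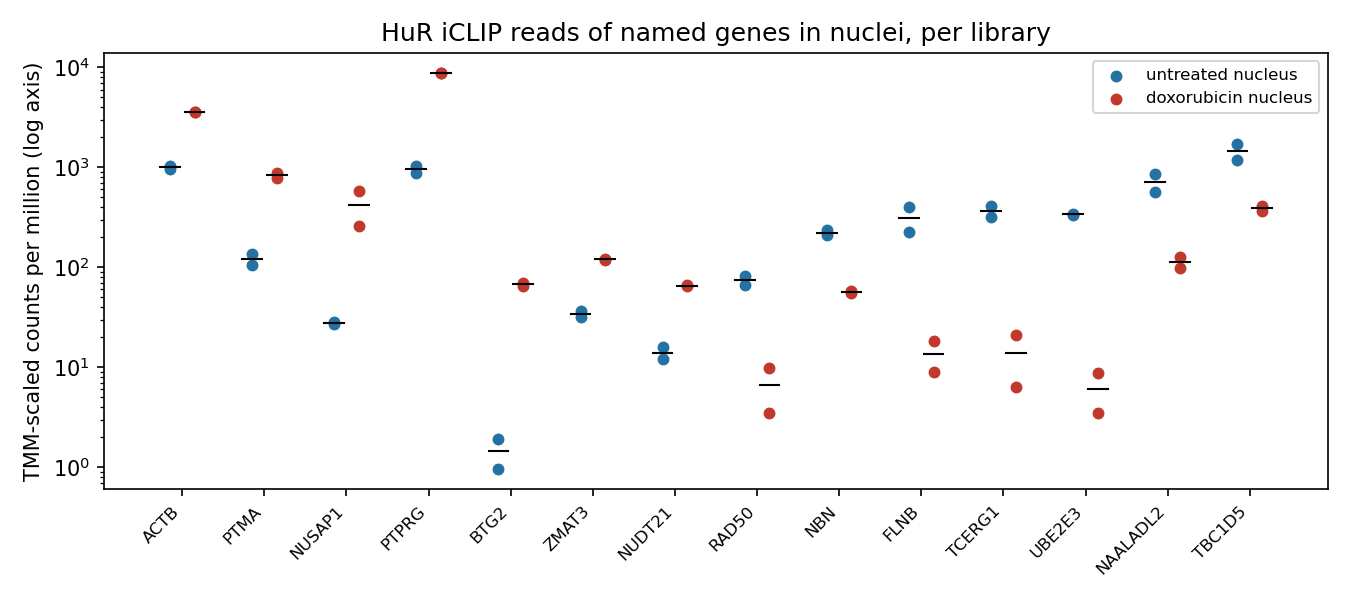
HuR-linked reads in nuclei for 14 named genes, as TMM-scaled CPM on a log axis, for untreated and doxorubicin-treated cells. Points are single libraries (n = 2 per group) and bars their means, and in every gene shown both doxorubicin libraries lie on the same side of both untreated ones, as for ACTB at 996 and 3574 CPM.

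Among the gene lists, members of the p53 target list lay higher in nuclei after doxorubicin and members of the DNA repair and estrogen response lists lower. The antiproliferative gene BTG2 rose from 1.44 ± 0.688 to 67.5 ± 2.63 CPM (log2 5.52 ± 1.04, adjusted p = 0.0296) and ZMAT3, a zinc finger RNA-binding protein gene, from 34.5 ± 3.52 to 120.1 ± 1.74 CPM (1.80 ± 0.38, adjusted p = 0.0427). These were the 2 of 21 tested p53 targets that passed over all genes, with 6 higher and 1 lower when adjusted over the list alone, and the list shifted upward (median log2 1.44, or 1.57 over the 17 members with peaks in both groups; camera adjusted p = 0.0296). CDKN1A, the p21 inhibitor, at 1.34 and MDM2, the p53 ubiquitin ligase, at 0.58 did not pass (adjusted p = 0.496 and 0.423). Of 28 DNA repair genes, RAD50 (74.0 ± 10.7 to 6.65 ± 4.47 CPM, adjusted p = 0.0350) and NBN (221 ± 18.2 to 56.3 ± 1.59 CPM, adjusted p = 0.0395), partners in the complex that binds broken DNA ends, fell. Adjusted over the list alone 3 repair genes fell, and the list median was −0.67 (camera adjusted p = 0.0296). None of 18 estrogen response genes passed over all genes in edgeR, while 8 lower and 1 higher did when adjusted over the list alone (median −1.55, camera adjusted p = 0.0388). The estrogen receptor gene ESR1 stood at 15991 ± 220.4 and 3311 ± 638 CPM and the stress-response factor XBP1 at 316 ± 20.2 and 85.9 ± 25.9 CPM in untreated and treated nuclei (adjusted p = 0.166 and 0.179). All 3 list calls were lost with an estimated correlation (adjusted p = 0.991 with an estimated correlation for each). They were also lost with fry (adjusted p = 0.139 for p53 targets, 0.204 for DNA repair and 0.119 for estrogen response).

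The remaining lists did not shift as sets in nuclei. Of 25 known HuR targets 2 rose, ACTB and PTMA (3 when adjusted over the list alone; camera adjusted p = 0.188), with median and mean of opposite sign (0.43 and −0.20). Of 25 mitosis genes NUSAP1 rose (1 higher and 1 lower over the list alone). Of 26 genes longer than 200 kb PTPRG rose, while NAALADL2 (−2.65 ± 0.51, adjusted p = 0.0325) and TBC1D5 (−1.89 ± 0.40, adjusted p = 0.0423) fell, the same count over the list alone. Of 23 genes of the cleavage and polyadenylation machinery, NUDT21, the 25 kDa subunit of cleavage factor I, rose from 14.01 ± 2.78 to 65.75 ± 0.220 CPM (adjusted p = 0.0484), and adjusted over the list alone 3 rose and 2 fell. None passed over all genes in edgeR among 26 RNA-binding and splicing factors (3 higher and 2 lower adjusted over the list alone), 13 nuclear long non-coding RNAs (1 higher over the list alone), or 37 ribosomal protein, 18 immediate-early, 13 replication-dependent histone, 6 small non-coding and 7 other-cell-type marker genes (0 each over the list alone). The histone list had camera adjusted p = 0.0727, with a median of −0.62 over the 6 members with peaks in both groups. ELAVL1 itself stood at 42.8 ± 12.3 and 56.9 ± 16.8 CPM, NEAT1 at 8876 ± 794 and 10379 ± 299, and cyclin D1, CCND1, at 240.2 ± 49.9 and 352 ± 9.95. MALAT1 stood at 21392 ± 217 and 45419 ± 7927 CPM (log2 1.09 ± 0.28, adjusted p = 0.0750). MYC had 154 and 76.9 CPM in untreated nuclei, and 1.45 and no listed peak after doxorubicin (adjusted p = 0.199).

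The nuclear count fell to 0 in edgeR when any 1 of the 4 nuclear libraries was left out, to 78 and 77 without the doxorubicin whole-cell libraries and 116 and 119 without the untreated whole-cell ones, and rose to 1093 and 1275 without doxorubicin cytosolic replicates 1 and 2 and 665 and 663 without the untreated ones. Leaving out peaks that overlapped an IgG peak gave 60, of which 41 were among the 369, with no listed ACTB peak in treated nuclei. The balance of directions also depended on the setting, with 73.4% of calls higher here, 61.4% of 1696 in DESeq2, 51.1% of 2816 without the 4 cytosolic libraries and 44.3% of 3802 (1685 higher and 2117 lower) with only the 4 nuclear libraries.

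Whole cells, which were not fractionated, moved in the same direction as nuclei in most genes. No single gene passed in edgeR (1676 below an unadjusted 0.05; 710 past the threshold in DESeq2). MRPS6 stood at 139.9 ± 50.7 CPM untreated and 1419.9 ± 347 after doxorubicin, and RBPJ, the DNA-binding effector of Notch signalling, at 209 ± 49.7 and 992 ± 117. USP50 had no listed untreated peak and 159 and 175 CPM after doxorubicin, MYRFL none and 103 and 139, and the zinc finger gene ZNF79 1.02 ± 0.131 and 83.0 ± 7.35. These were the 5 smallest p-values, each with adjusted p = 0.0811. PTPRG stood at 764 ± 239 and 4243 ± 151 CPM (adjusted p = 0.102), ACTB at 3257 ± 50.3 and 5871 ± 887 (0.164), MALAT1 at 18911 ± 5688 and 29782 ± 665 (0.354) and ESR1 at 14320 ± 8215 and 2376 ± 625 (0.225). Across the 5065 genes with peaks in all 12 HuR libraries, log2 fold changes in whole cells and nuclei, which share no library, correlated with Pearson r = 0.906 and Spearman rho = 0.892, and 84.9% had the same sign. Genes are not independent replicates.

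**Figure D2:**
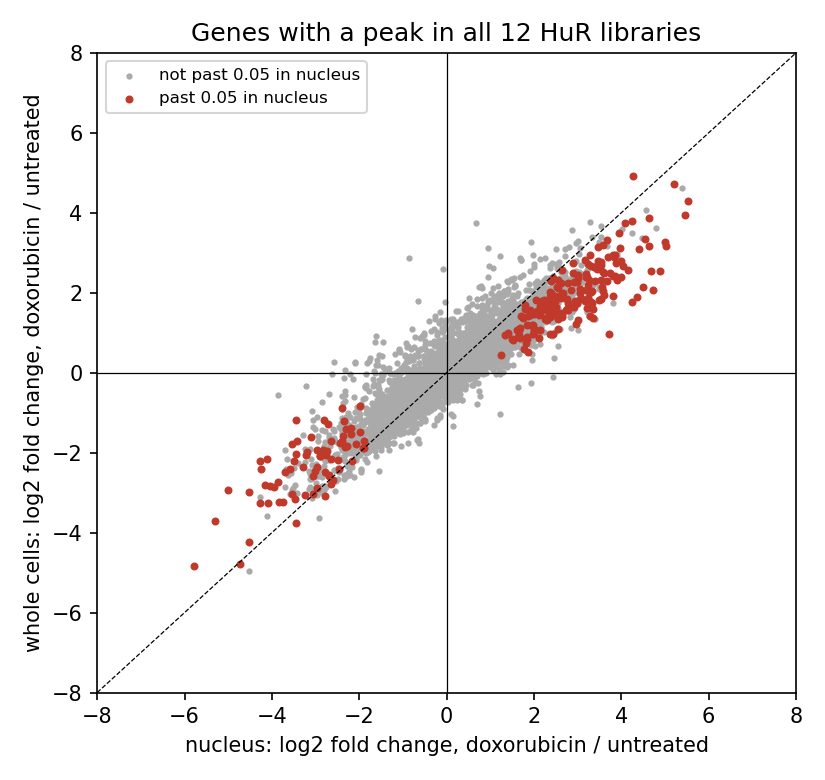
Log2 fold change with doxorubicin in nuclei (x axis) against whole cells (y axis) for the 5065 genes with a listed peak in all 12 HuR libraries. Each point is a gene, red points passed an adjusted p of 0.05 in nuclei, and the cloud follows the diagonal (Pearson r = 0.906 across genes).

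The DNA repair list lay lower in whole cells (median −0.76, camera adjusted p = 0.0102; 1 lower over the list alone), the p53 target list higher (median 1.14 over 20 members with peaks in both groups, adjusted p = 0.0158; 3 higher over the list alone) and the replication histone list lower (median −1.50 over 9 such members, adjusted p = 0.0393; none over the list alone). All 3 calls were lost with an estimated correlation (adjusted p = 0.991 with an estimated correlation). They were also lost with fry (adjusted p = 0.273 for DNA repair, 0.130 for p53 targets and 0.385 for histones). No member passed singly in edgeR. The repair helicase BRIP1 stood at 7592 ± 946 and 3587 ± 571 CPM (adjusted p = 0.434) and CDKN1A at 11.6 ± 9.58 and 46.4 ± 28.0 (adjusted p = 0.386). The count over all genes, 0 of 12539 in edgeR, was 1792 without the 4 cytosolic libraries, 1053 with only the 4 whole-cell libraries, 199 and 273 without doxorubicin cytosolic replicates 1 and 2, and 53 and 31 without the untreated ones.

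In cytosol, no gene passed with doxorubicin. Peaks overlapping an IgG peak held 82.9% and 88.5% of the untreated and 88.5% and 84.5% of the treated cytosolic reads. The lack of calls is therefore not read as unchanged HuR contact in cytosol. ACTB stood at 28161 ± 1932 CPM untreated and 25279 ± 957 after doxorubicin, CCND1 at 1634 ± 177 and 1748 ± 385, and ELAVL1 at 267 ± 90.3 and 272.5 ± 73.8. MDM2 stood at 851 ± 10.1 and 739 ± 100.1, and MALAT1 at 6745 ± 1189 and 4680.2 ± 1086. Each of the 5 had adjusted p = 1. The smallest adjusted p was 0.351, for genes such as the kinetochore gene CENPK, with 11.1 and 4.01 CPM untreated and no listed peak after doxorubicin. The list of genes longer than 200 kb lay lower (median −0.30, camera adjusted p = 0.0410). That call was lost with an estimated correlation (adjusted p = 0.991) and with fry (adjusted p = 0.659). In this list 0 of 26 members passed the threshold over all genes and adjusted over the list alone. In edgeR 0 genes passed, with 602 below an unadjusted 0.05 and 6 past the threshold in DESeq2. Leaving out doxorubicin cytosolic replicate 2 gave 1383 genes, 6 higher and 1377 lower. Untreated cytosolic replicate 1 correlated across genes with doxorubicin replicate 2 (Spearman 0.947) more closely than with untreated replicate 2 (0.876) or doxorubicin replicate 1 (0.831).

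Averaged over the 3 preparations (6 against 6 libraries), genes higher with doxorubicin included the centromere protein gene CENPL (log2 2.18 ± 0.34, adjusted p = 0.0186), the unconventional myosin MYO10 (1.52 ± 0.28, 0.0262), the chromatin gene MBD3 (1.05 ± 0.23, 0.0472) and ACTB (0.85 ± 0.12, 0.0158). The mismatch repair gene MSH3 (−2.03 ± 0.34, adjusted p = 0.0217), the endosomal gene RABEP1 (−2.23 ± 0.34, 0.0176), TCAF1 (−2.37 ± 0.35, 0.0159), TBC1D9 (−1.84 ± 0.28, 0.0176), CRADD (−3.36 ± 0.38, 0.0145) and CFDP1 (−1.46 ± 0.24, 0.0209) fell. In the polyadenylation list NUDT21 (1.35 ± 0.28) and CSTF3 (1.03 ± 0.23) rose and SCAF8 (−2.20 ± 0.48) and CPSF6 (adjusted p = 0.0427) fell. The DNA repair (adjusted p = 0.00646), p53 target (0.0165) and estrogen response (0.0388) lists shifted in the directions seen in nuclei, each with adjusted p = 0.991 with an estimated correlation. With fry their adjusted p-values were 0.130, 0.130 and 0.0874. In all 385 genes passed, 238 higher and 147 lower (1871 in DESeq2), and 10 of 100 splits of the libraries within preparation, the real one included, called at least as many. Of the other 9, 7 kept the real grouping in at least 2 preparations, where a preparation with its 2 treatments exchanged also counts as kept. The majority was lower with peaks of at least 10 reads (97 higher and 113 lower), without IgG-overlapping peaks (76 and 99) and without doxorubicin cytosolic replicate 2 (579 and 1928). None passed in edgeR without any 1 of the nuclear or whole-cell libraries, while 774 and 2507 passed without doxorubicin cytosolic replicates 1 and 2 and 679 without untreated cytosolic replicate 2.

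The difference between the doxorubicin effects in nucleus and cytosol bears on the compartment question of the series, with the limit that most cytosolic reads lay in peaks overlapping an IgG peak. It was largest by p-value for MRPS6 (log2 5.07 ± 0.61, adjusted p = 0.0878), CMTM6 (4.84 ± 0.65, 0.0965), the ubiquitin ligase adaptor KLHL11 (4.41 ± 0.64, 0.0965) and ACTB (2.00 ± 0.30, 0.0965), and for CDC45, which had no listed peak in treated nuclei (adjusted p = 0.0878). None of these passed, and the p53 target list missed the threshold (camera adjusted p = 0.0515). In edgeR 0 genes passed, with 1646 below an unadjusted 0.05 and 709 past the threshold in DESeq2. The count was 103 and 1386 without doxorubicin cytosolic replicates 1 and 2 and 138 without untreated cytosolic replicate 1.

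Because the series concerns polyadenylation inside introns, reads were also split by position within the gene. The gene end was the last 5 kb before the annotated 3′ end plus anything downstream, and the body everything upstream of it, exons and introns together. In untreated nuclei 24.8% ± 0.373 of the reads lay in gene ends and after doxorubicin 41.0% ± 3.50 (SD, n = 2). In whole cells the shares were 35.6% ± 4.07 and 53.3% ± 0.201, and in cytosol 85.0% ± 4.56 and 85.9% ± 0.866. The IgG libraries had 88.1% and 42.7%. Over the 3 preparations the gene-end share was 11.6 percentage points higher with doxorubicin, higher in both libraries of nuclei and whole cells (exact two-sided permutation within preparation, p = 0.0278, smallest possible 0.00926; adjusted over 10 such comparisons 0.0694). The share of reads in genes of at least 200 kb differed by −5.61 points, from 31.5% ± 1.07 to 24.0% ± 2.53 in nuclei and from 27.2% ± 2.27 to 18.3% ± 0.930 in whole cells (exact p = 0.0185, adjusted 0.0694). The MALAT1 share was 1.06 points higher (2.28% ± 0.0615 to 4.39% ± 1.04 in nuclei; exact p = 0.0463, adjusted 0.0694), that of all non-coding genes 1.48 points higher (exact p = 0.0648, adjusted 0.0720), and the NEAT1 share differed by −0.0698 points (exact p = 0.574). Counted as peaks in place of reads, the gene-end difference was 6.80 points (exact p = 0.231), and without untreated cytosolic replicate 1 it was 10.5 points (exact p = 0.0556).

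**Figure D3:**
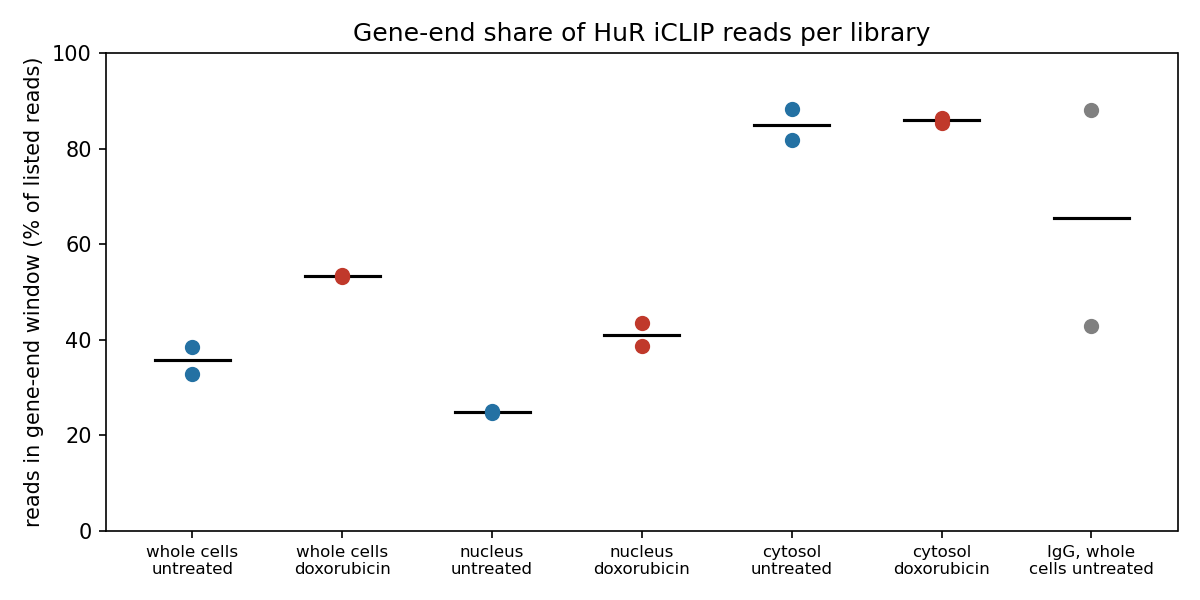
Share of reads in listed peaks that lay in gene ends (the last 5 kb before the annotated 3′ end and downstream), in percent, for each HuR and IgG library. Points are libraries and bars group means (n = 2 each), with nuclei at 24.8% untreated and 41.0% after doxorubicin, and cytosol at 85.0% and 85.9%.

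The shift was also tested gene by gene in 6256 genes with both features. In nuclei the end gained reads relative to the body in 745 genes and the body relative to the end in 30, with a median body minus end log2 difference of −2.33. In whole cells 144 genes shifted to the end and 6 to the body (median −1.89), in cytosol 2 and 1 (median 0), and on average over preparations 708 and 24. Of single features in nuclei, 160 gene ends rose and 2 fell, while 32 gene bodies rose and 52 fell. These single-feature calls were all lost in edgeR without any 1 nuclear or whole-cell library, with a replicate block and with a window of 10 kb, and with total-read scaling 716 ends rose and 17 fell and 145 bodies rose and 242 fell. The nuclear count of 775 was 51 and 78 without untreated nuclear replicates 1 and 2, 77 and 97 without the doxorubicin ones, 367 and 416 without the untreated whole-cell ones, and up to 1606 without a doxorubicin cytosolic library. The whole-cell count of 150 fell to 0 without any 1 whole-cell or untreated nuclear library and rose to 2081 without the 4 cytosolic libraries.

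Nucleus against cytosol in untreated cells asks where HuR-linked reads of each gene lay. Peaks overlapping an IgG peak held 82.9% and 88.5% of the reads of the untreated cytosolic libraries, against 33.3% and 33.0% in untreated nuclei. After doxorubicin these shares were 88.5% and 84.5% in cytosol and 42.9% and 38.9% in nuclei. A higher cytosolic level is therefore not told apart from background by these reads. ACTB, PTMA and ELAVL1 were higher in cytosol. ACTB stood at 996 ± 36.7 CPM in nuclei and 28161 ± 1932 in cytosol (log2 −4.82 ± 0.25, adjusted p = 7.8e-05), PTMA at 121 ± 20.4 and 5042 ± 1946 (−5.38 ± 0.49) and ELAVL1 at 42.8 ± 12.3 and 267 ± 90.3 (−2.64 ± 0.49, adjusted p = 0.00468). B2M, the light chain of MHC class I, had no listed nuclear peak and 66.2 and 278 CPM in cytosol, as did the zinc transporter gene SLC30A1 with 35.2 and 793.5. Higher in nuclei were MALAT1 (21392 ± 217 against 6745 ± 1189 CPM; 1.67 ± 0.29, adjusted p = 0.00350) and NEAT1 (8876 ± 794 against 1454 ± 1238; 2.61 ± 0.75, adjusted p = 0.0282). RASA2, a Ras GTPase-activating protein gene, had 205 and 218.5 CPM in nuclei and no listed cytosolic peak, as did the polycomb gene EED with 143 and 154.

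By list, 15 of 25 known HuR targets were lower in nuclei than in cytosol and 1 higher (median −2.63 over 24 members with peaks in both; camera adjusted p = 2.97e-05; over the list alone 15 and 2), among them CCND1 (−2.77 ± 0.32), thrombospondin 1, THBS1 (−3.79 ± 0.57), CCNA2 (−3.69 ± 0.58) and CDKN1A (−3.58 ± 0.98). BCL2, the apoptosis inhibitor, was the exception, with 11.5 and 14.5 CPM in nuclei and no listed cytosolic peak. Of 26 genes longer than 200 kb 17 were higher in nuclei and none lower (median 2.98, camera adjusted p = 0.00289; 19 over the list alone), such as the ribosylhydrolase gene MACROD2 (5.81 ± 1.44), IMMP2L (5.18 ± 0.84), the exocyst gene EXOC4 (5.12 ± 0.50) and RAD51B (4.89 ± 1.32). Both list calls were lost with an estimated correlation (adjusted p = 0.991 with an estimated correlation). Of 28 DNA repair genes 12 were higher in nuclei and 2 lower (12 and 3 over the list alone), with WRN, MLH1, BLM and XRCC1 lacking a listed cytosolic peak. Among estrogen response genes 5 of 18 were lower in nuclei (5 over the list alone), including SLC39A6 (−4.48 ± 0.70), IGFBP4 (−4.35 ± 0.54) and XBP1 (−2.80 ± 0.71). Of 26 RNA-binding factors 9 were lower and 2 higher (9 and 4 over the list alone), with HNRNPA1 (−3.60 ± 0.67) and HNRNPK (−3.45 ± 0.45) lower and SRSF11 (3.63 ± 0.79) higher. The polyadenylation list split as well, with 7 of 23 higher, such as SCAF8 (3.68 ± 0.88) and CDK13 (3.46 ± 0.61), and 3 lower, such as NUDT21 (−4.71 ± 0.55). In the nuclear long non-coding RNA list 5 of 13 were higher and 2 lower, TUG1 (−4.19 ± 0.57) and LINC00657 (−3.46 ± 0.52).

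Of 21 p53 targets 3 were higher in nuclei and 6 lower (4 and 6 over the list alone), including CCNG1 (−4.94 ± 1.20), and of 25 mitosis genes 1 was higher and 7 lower (2 and 7), including CCNB1 (−2.97 ± 0.84). Ribosomal protein genes gave 1 higher and 5 lower of 37 (0 and 2), such as RPS11 (−5.07 ± 1.01) and RPL23 (−3.96 ± 0.89), and small non-coding RNAs 3 higher and 1 lower of 6, with SCARNA2 (2.58 ± 0.61) and RNU12 (2.55 ± 0.69) higher and RPPH1 (−1.98 ± 0.56) lower. Immediate-early genes gave 1 lower of 18, SGK1 (−4.33 ± 0.75), histones 1 higher and 1 lower of 13, and other-cell-type markers 1 higher of 7, the macrophage marker CD68.

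In all 3612 genes passed in untreated cells, 1997 higher in nuclei, of which 1285 had no listed cytosolic peak, and 1615 lower, of which 137 had no listed nuclear peak. Over genes with peaks on both sides the medians were 3.25 (712 genes) and −3.37 (1478 genes). The median of all genes was 1.14 with TMM, 1.35 with DESeq2 scaling, 1.50 with total reads and 0.84 with upper-quartile scaling, while fold changes and calls are given against 0, and 65.4% of DESeq2's 5627 calls were higher in place of 55.3%. The count changed when single libraries were left out, with the range given in the closing section. It was 1337 without IgG-overlapping peaks, which left ACTB without a listed cytosolic peak. ELAVL1, CCND1, NEAT1, IGFBP4, HNRNPA1, HNRNPK and RNU12 then turned to the opposite sign. NEAT1 was left with 133 and 33 nuclear and 95 and 261 cytosolic reads, too few to read as a direction. By number of peaks ELAVL1, MALAT1, NEAT1 and CCND1 turned, but that number is not a level, since a wide peak counts once.

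After doxorubicin the nuclear excess of MALAT1 was 45419 ± 7927 against 4680.2 ± 1086 CPM (log2 3.28 ± 0.31, adjusted p = 0.00153) and that of NEAT1 10379 ± 299 against 460 ± 286 (4.49 ± 0.82, adjusted p = 0.00636). ACTB (−2.82 ± 0.23, adjusted p = 0.00153), CCND1 (−2.31 ± 0.32) and ELAVL1 (−2.26 ± 0.48) were lower in nuclei. So were the antiproliferative gene TOB1 (29.3 and 48.2 CPM in nuclei, 75.4 and 2469 in cytosol), the Rho GTPase gene RHOB (6.97 and 14.6 against 47.9 and 725) and the tight junction gene CLDN4 (none and 2.14 against 13.8 and 158), where cytosolic replicate 2 carried most of the difference. SECISBP2, a selenoprotein translation factor gene, had 1386 and 855 CPM in nuclei and no listed cytosolic peak. None of 25 known HuR targets was higher and 12 were lower (camera adjusted p = 2.97e-05), 16 of 26 long genes were higher (0.00207), 7 of 18 estrogen response genes (0.000490) and 3 of 18 immediate-early genes (0.0164) were lower, and 3 ribosomal protein genes were higher and 2 lower of 37 (median −0.93 over 30 members with peaks in both, 0.0165). Each of these calls had adjusted p = 0.991 with an estimated correlation, and over the list alone 12, 20, 7, 5 and 0 members passed. In all 3097 genes passed, 1901 higher (987 with no listed cytosolic peak) and 1196 lower (81 with no listed nuclear peak). The count was 1267 and 1527 without doxorubicin nuclear replicates 1 and 2, 5967 without doxorubicin cytosolic replicate 2, 5731 in DESeq2 and 0 with only the 4 libraries compared, and 49.3% of calls were higher with upper-quartile scaling in place of 61.4%. NEAT1 turned to −1.76 without IgG-overlapping peaks and −3.54 by number of peaks. ELAVL1 turned to 1.33 without IgG-overlapping peaks and CCND1 to 0.0933 by number of peaks. These turned values rest on few leftover reads or on peak numbers, which are not levels, and are not read as directions.

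Averaged over both treatments (4 against 4 libraries) 3678 genes were higher in nuclei and 2243 lower. MALAT1 stood at log2 2.47 ± 0.21, NEAT1 at 3.55 ± 0.55, ACTB at −3.82 ± 0.17, CCND1 at −2.54 ± 0.23, ELAVL1 at −2.45 ± 0.34 and CDKN1A at −2.99 ± 0.67, the last with adjusted p = 0.00625 and the others below it. NEAT1 turned to −2.52 without IgG-overlapping peaks and −4.43 by number of peaks. ELAVL1 turned to 2.32 and 0.0333. By number of peaks MALAT1 turned to −0.30 and CCND1 to 0.32, while ACTB had no listed cytosolic peak without IgG-overlapping peaks. The turned values rest on few leftover reads or on peak numbers, and are not read as directions. The RNA-binding list joined the lists past the threshold, with 12 of 26 lower and 7 higher (camera adjusted p = 0.0419; 0.991 as the adjusted p with an estimated correlation). The gene-end share of reads differed by −52.5 points between nuclei and cytosol and was lower in every nuclear library than in every cytosolic one (exact two-sided permutation within treatment, p = 0.0556, the smallest possible here, so that this comparison could not pass 0.05).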

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

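The settings without the 4 cytosolic libraries, with at least 15 reads per peak, with peaks counted per gene and with gene-end windows of 2 and 10 kb were chosen after the results were seen. Counts are genes past an adjusted p of 0.05, in the order whole cells, nucleus, cytosol, mean of preparations (doxorubicin), nucleus against cytosol untreated, treated and mean, and the difference of effects; the main values are 0, 369, 0, 385, 3612, 3097, 5921 and 0. The cause of each change was not tested, except that settings with fewer libraries or reads test less data. With 2 libraries per group the spread is pooled, so a lone library is assumed to vary like the other groups. Depth may also limit the calls, since absent peaks are censored, but this was not tested.

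DESeq2 gave 710, 1696, 6, 1871, 5627, 5731, 7469 and 709, and 2995 for HuR against IgG. Total-read scaling gave 8 in whole cells and 2 for the difference of effects, upper-quartile scaling 6 in whole cells, and no filter 25 and 8. Over genes with a peak in all 12 libraries the counts were 180 in whole cells, 806 in nuclei, 945 for the mean, 3585 for the mean nucleus against cytosol and 169 for the difference of effects. With at least 10 reads per peak, 138 passed in nuclei, 210 for the mean, 2057 for nucleus against cytosol after doxorubicin and 4075 for HuR against IgG; with at least 15 reads, 91, 197, 2155 (untreated) and 1479 (doxorubicin). Without IgG-overlapping peaks, 60 passed in nuclei, 175 for the mean, and 1337, 1395 and 3598 for nucleus against cytosol untreated, treated and mean. With only the libraries compared, 1053 passed in whole cells, 3802 in nuclei and 0 for nucleus against cytosol after doxorubicin. Without the 4 cytosolic libraries, 1792 passed in whole cells and 2816 in nuclei, 368 of them among the 369. Peaks counted per gene gave 1482, 2144 and 1176 for whole cells, nuclei and the mean, 3571 for the mean nucleus against cytosol and 180 for the difference of effects.

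For genes shifting between body and end (main 150, 775, 3 and 732), whole cells gave 375 with total reads, 63 without the filter, 280 in genes with all 12 libraries, 1894 with only the libraries compared, 2081 without the cytosolic libraries and 612 with peaks per feature. Nuclei gave 430 in genes with all 12 libraries, 2880 with only the libraries compared and 2639 without the cytosolic libraries, and the mean 443 in genes with all 12 libraries. Cytosol gave 12 with total reads, 0 in genes with all 12 libraries, with only the libraries compared and with peaks per feature, 5 with a window of 2 kb and 1 with 10 kb (edgeR). As a share of peaks, the gene-end difference was 6.80 points. Gene lists called were 0 with an estimated correlation and 12 with fry, all 12 for nucleus against cytosol, against 23.

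The labels do not say that replicate numbers mark a shared batch, so the numbers are not treated as pairs (correlation of same-numbered libraries between treatments −0.375 in cytosol, 0.324 in whole cells and 0.0824 in nuclei; up to 0.157 between preparations). A replicate block gave 150 genes in nuclei, 163 for the mean and 0 body and end shifts in whole cells, and a block by the number in the file names 0 in nuclei, 0 for the mean, and 2067 and 1527 for nucleus against cytosol untreated and treated. A block pairing the cytosolic libraries crosswise, added after the results were seen, called 0 genes in cytosol with all 12 libraries and with the 4 cytosolic ones (edgeR).

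Leave-one-out ranges were 0 to 273 in whole cells, 0 to 1275 in nuclei, 0 to 1383 in cytosol, 0 to 2507 for the mean, 1694 to 5612, 1267 to 5967 and 4223 to 7762 for nucleus against cytosol, 0 to 1386 for the difference of effects and 0 to 7318 for HuR against IgG. For body and end shifts they were 0 to 802, 51 to 1606, 0 to 211 and 226 to 1426, and for the gene-end share 10.5 to 12.7 points with doxorubicin and −54.1 to −50.9 between nucleus and cytosol.

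Of the settings for single genes and lists, 2821 gave the same result, 557 were weaker, 125 stronger, 34 moved and 28 reversed. Without IgG-overlapping peaks, ACTB kept listed peaks only in untreated nuclei and whole cells and SGK1 none in untreated cytosol or treated nuclei, so their fitted values here are neither folds nor directions (ACTB with doxorubicin −8.56 in nuclei and −5.90 for the mean, and for nucleus against cytosol 8.56 untreated and 4.28 in the mean; SGK1 7.002 untreated). Nucleus against cytosol changed sign in untreated cells for ELAVL1 (3.30), NEAT1 (−3.28), CCND1 (1.00), IGFBP4 (1.34), HNRNPA1 (2.65), HNRNPK (0.10) and RNU12 (−1.76), after doxorubicin for ELAVL1 (1.33) and NEAT1 (−1.76), and in the mean for ELAVL1 (2.32) and NEAT1 (−2.52). Several of these signs rest on few leftover reads. In untreated cells NEAT1 kept 133 and 33 reads in nuclei and 95 and 261 in cytosol. As listed, 1 untreated nuclear NEAT1 peak alone held 223507 reads. Untreated cytosol kept 0 and 21 reads for ELAVL1 and 32 and 0 for RNU12. Such values do not show that the nuclear excess of NEAT1 reverses. Counted as peaks, doxorubicin reversed CCND1 in nuclei (−1.55) and ACTB in the mean (−0.0545). Nucleus against cytosol reversed for ELAVL1 (0.11), MALAT1 (−0.60), NEAT1 (−5.33) and CCND1 (0.54) untreated, NEAT1 (−3.54) and CCND1 (0.0933) after doxorubicin, and ELAVL1 (0.0333), MALAT1 (−0.30), NEAT1 (−4.43) and CCND1 (0.32) in the mean. The number of peaks is not a level, since a wide peak counts once. In untreated nuclear replicate 1 the most-read NEAT1 peak was 17850 nt wide and the most-read MALAT1 peak 7300 nt. These reversals therefore do not bear on where most reads lay.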

Other observations

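The tests of carry-over, nuclear RNA without shared libraries, IgG background, assignment of positions, wider neighbour windows and both sets of splits were chosen only after the result was seen.

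Gene length went with the doxorubicin effect in nuclei. This was examined in the 5065 genes with a listed peak in all 12 HuR libraries. The Spearman correlation of log2 fold change with gene length was −0.193 in nuclei and −0.218 in whole cells, and 0.343 for nucleus against cytosol in untreated cells. In nuclei, the 686 of these genes shorter than 10 kb had a median log2 fold change of 0.29 and the 420 of at least 200 kb one of −0.15. Genes of at least 100 kb were cut into 5 equal parts of the gene, the last counted without the gene end of 5 kb. That last part held 10.9% of body reads in both untreated nuclear libraries and 16.1% and 16.3% after doxorubicin. The first part held 30.1% and 30.2% against 27.2% and 24.7%. Whole cells had 11.4% and 12.2% in the last part untreated and 16.2% and 17.6% after doxorubicin.

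The gene-end share of HuR reads was higher with doxorubicin in nuclei (by 16.2 points) and whole cells. Depth and the peak threshold are argued against only as far as they act on peaks already listed. After thinning the listed peaks to equal reads and keeping those of at least 15 reads, the difference was 18.3 points (16.9 as listed). Every doxorubicin library then lay above every untreated one of its preparation (exact permutation p = 0.0556, the smallest possible). Peaks were not called again on thinned reads, so an effect of depth on which positions were listed stays open. Cytosolic RNA carried into the nuclear fraction cannot be the cause in whole cells, which were not fractionated and differed by 17.7 points. For the nuclear rise it stays open, since whole cells hold cytosolic RNA too and their rise can have another source. IgG-like background stays open. Leaving out peaks that overlap an IgG peak cannot remove background too weak to be listed in the small IgG libraries. Without IgG-overlapping peaks the difference was 8.65 points in nuclei and 10.6 in whole cells, which is 88.9% and 87.3% of the lower untreated shares. A hypothesis that stays open is biological, that less unprocessed RNA, or more RNA ending near the 3′ end, may be available to HuR after doxorubicin, and without RNA libraries contact and RNA amount cannot be separated.

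Cytosolic libraries resembled the other treatment more than their own replicate, with Spearman 0.947 for untreated replicate 1 and doxorubicin replicate 2 and 0.911 for the other crossed pair, against 0.876 and 0.8345 within groups. Same-numbered pairs split, with 0.831 for replicates 1 and 0.913 for replicates 2. Different amounts of nuclear RNA in the fractions stay open. The crossed difference correlated with nucleus minus cytosol across genes (Pearson r = 0.477), but both are built from the same 4 cytosolic libraries, so that value decides nothing. With nucleus minus whole cells, which shares no library with it, r was 0.218, under the 0.3 set for that test. Swapped labels cannot be told apart from this. The crossed difference correlated at −0.246 with the nuclear doxorubicin effect, under the bound of 0.3 set beforehand, but that bound was wrong because it took the nuclear effect of doxorubicin for the cytosolic one.

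In nuclei, 55 genes held reads after doxorubicin and had no listed peak in untreated nuclei, although 28 had one in untreated whole cells, 25 in untreated cytosol and 31 in either. At the doxorubicin level, 69.1% would hold at least 10 times the minimum reads per peak in both untreated nuclear libraries. That is a projection of reads summed over a gene's peaks, set against the minimum of a single peak. The genes were also picked as called, which favours high levels. The peak threshold therefore stays open as an explanation. Assignment of 1 position to different genes is argued against, found in 0 of 1010944 bins. Transcription reading through from an upstream gene is a candidate explanation that stays open. An upstream neighbour lay within 10 kb for 18.2% of the genes (Clopper-Pearson 95% interval 9.08 to 30.9), against a median of 12.7% in random sets (p = 0.208 from 10000 sets), and over wider windows the shares were 41.8% against 25.5% (25 kb, unadjusted p = 0.00700), 50.9% against 38.2% (50 kb, p = 0.0313) and 65.5% against 52.7% (100 kb, p = 0.0346), with a lowest adjusted p of 12 tests of 0.0840. AMPD1, for example, lies 8846 nt downstream of NRAS and USP50 10454 nt downstream of TRPM7.

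For the mean doxorubicin comparison, 10 of 100 splits within preparation, the real one included, gave at least the real 385 genes, the highest other 3330, so chance is not excluded by that count. Of the other 9, 7 kept the real grouping in at least 2 preparations and 6 regrouped only the cytosol. A preparation with its 2 treatments exchanged counts as kept here. A split that regrouped no preparation but exchanged treatments in this way called 485 genes, and another such split called 0. Partly wrong treatment labels could thus call more genes than the real ones, and the source of these counts was not tested. The 30 splits that regrouped all 3 preparations gave at most 259. For the mean nucleus against cytosol comparison, the 18 splits are too few for a share under 0.05 (real value 5921, highest other 0, 1 split as large).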
